A study of Mus musculus with 6 samples.

How the data were processed

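Gene expression was measured on whole-transcript Affymetrix arrays in mouse pre-B acute lymphoblastic leukaemia cells transformed with the BCR-ABL1 fusion kinase. The cells came from the C57Bl/6 strain and carried a floxed Bcor allele on the X chromosome of a male, so that Cre recombinase can remove the floxed part from the only copy. Per the labels, the cells were transduced with a vector for Cre-ERT2, a Cre recombinase that tamoxifen activates, or with the matching ERT2 vector that lacks Cre. Both groups received 4-hydroxytamoxifen at 0.5 micromolar for 2 days, and their RNA, taken from cells selected with puromycin, was labelled with biotin by the array maker's protocol. There were 3 arrays of each group. The labels do not say that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

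The deposited values are log2 expression values per probe set. RMA and Partek 6.5 are named in the submitters' processing notes, with no role or order given. The background setting and the genome build were not given in the sources used here. Their range fits log2 RMA values, and they are not centred per probe set. Because the probe-level intensities were not used here, the arrays' own detection limits are unknown and no probe set was called absent. The number of arrays limits the precision: the median residual SD per gene was 0.0587 and the median standard error of a log2 fold change was 0.0477.

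Probe sets were named with the platform's annotation. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed with a gene. Of the unlisted probe sets, 6617 have numbers below the first named probe set and were treated as controls, which is a working definition. The other 5529 were left out of the gene tests. Gene identifiers of 21698 probe sets matched the GRCm38.p6 gene table, 91 did not match, and 0 symbols needed an update. That table was used for names and for which genes neighbour each other. Each gene was represented by its single-symbol probe set of highest mean, which gave 19938 genes, 999 of them with more than 1 probe set. No gene had probe sets called in opposite directions (0 genes). A gene covered only by a probe set with several symbols is not reported here, and this leaves out Cdkn1a and Trp53, among other list members.

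Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend) on all 6 arrays, as Cre-ERT2 minus ERT2. Benjamini-Hochberg adjustment covered all 19938 genes, and a gene was called at an adjusted p under 0.05. Values are means with the SD over 3 arrays per group, and the error of a log2 fold change is the moderated standard error (SE). Tables were read with the R package data.table, version 1.17.8, and plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

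A set of 31 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists. Camera asks whether the genes of a list rank above or below the other genes. Members past the threshold were counted over all genes and adjusted over the list alone. As alternatives, camera was run with the correlation estimated for each list, and fry tested whether a list's genes move, on balance, in 1 direction. The lists, the tests, the alternatives and the rule for named genes were set before the data were examined.

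The rule named Bcor first. It then took the 12 largest rises and the 12 largest falls among called genes whose Cre-ERT2 arrays all lay above or all below the ERT2 arrays, leaving out clone-style, predicted-gene, olfactory and vomeronasal receptor and small RNA names. From each list it took up to 4 called members of largest absolute change, or, where none was called, the 2 of smallest p. From the marker lists of other cell types it also took the 2 members of highest mean level. Members named beyond this rule are marked as chosen after their values were seen.

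The alternatives were the replicate number as a block, an intensity trend in eBayes, array weights, quantile normalization and median centring of the deposited values, leaving out the dimmest 30% or 50% of genes, the mean of a gene's probe sets, all non-control probe sets, an adjusted p of 0.1, a log2 fold change of at least 1, limma's treat against 0.2, and each array left out in turn. Cyclic loess between arrays was added after the data were seen.

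The pipeline was tested on simulated data for the same comparison of 19938 genes. It recovered 48% of genes changed by 0.25 on the log2 scale, 98% of those changed by 0.5 and 100% of those changed by 1. It called 8 unchanged genes, 4.42% of its calls. With no list changed it called 0 lists. A list raised by 0.2 was called, and 1 other list was called with it. The simulated noise was independent between genes. These list results therefore do not show how the preset correlation behaves where the genes of a list vary together. Only 50 genes were changed by 0.25, 50 by 0.5 and 100 by 1, while 1402 were called in the data. Noise was also equal on all simulated arrays. The shares recovered and falsely called hold for that setting and may differ in the data.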

Results

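The data were 6 arrays of BCR-ABL1-transformed mouse pre-B leukaemia cells with a floxed Bcor allele, 3 carrying Cre-ERT2 and 3 carrying the ERT2 control vector, all after 2 days of 4-hydroxytamoxifen. Bcor encodes a corepressor that binds the repressor BCL6 and is a subunit of the polycomb complex PRC1.1. The comparison asks about the role of Bcor in gene expression in these cells, following the series title. The median log2 value per array was 8.64, 8.66 and 8.61 for ERT2 replicates 1 to 3, and 8.61, 8.62 and 8.68 for Cre-ERT2 replicates 1 to 3. The first principal component held 51.9% of the variance and separated the groups, and the second held 20.6%.

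Bcor itself was lower in every Cre-ERT2 array. Its log2 level was 10.07, 10.11 and 10.17 in the ERT2 arrays and 9.08, 9.22 and 9.18 in the Cre-ERT2 arrays. The means were 10.12 ± 0.0517 and 9.16 ± 0.0716 (SD, 3 arrays each), a log2 fold change of -0.96 (SE 0.0491, limma adjusted p = 2.11e-05). The Cre-ERT2 level was 51.5% of the ERT2 level. The array carries 1 probe set for Bcor, and the labels do not say which part of the gene is floxed, so part of the probe set may lie outside the deleted part and the remaining signal does not measure the share of undeleted cells.

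The largest fall was in Rgs18, a regulator that shortens G protein signalling in blood cells, which was 5.62-fold lower with Cre-ERT2 (10.75 ± 0.0982 in ERT2 against 8.25 ± 0.131, SD, log2). Its relative Rgs1 fell 2.05-fold. The largest rise was in Ly6f, a small membrane-anchored protein of the Ly6 family, which was 3.62-fold higher (9.61 ± 0.0296 against 11.46 ± 0.0698). Alox5ap, which activates 5-lipoxygenase in leukotriene synthesis, rose 2.83-fold, and Icosl, the ligand of the costimulatory receptor ICOS, rose 2.44-fold. Across all 19938 genes, limma called 1402, of which 808 were higher and 594 lower in Cre-ERT2.

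Ffar2, a receptor for short-chain fatty acids, rose by 1.22 on the log2 scale (SE 0.0405). Cd74, the invariant chain of class II MHC, rose by 1.09 (SE 0.0649), Chn2, a GTPase-activating protein for Rac, by 1.08 (SE 0.0538), and the small GTPase Rhoq by 1.06 (SE 0.0379). Id2, which blocks DNA binding of E proteins, rose by 1.03 (SE 0.0669). Pcbd1, an enzyme of tetrahydrobiopterin recycling, and Tmed6, of the p24 cargo receptor family, each rose by 1.18. The centromere protein gene Cenpv rose by 1.11 and the histone H2B gene H2bc4 by 1.05. Adjusted p for these 9 genes, Ly6f, Alox5ap and Icosl lay between 8.76e-07 (Ly6f) and 0.000226 (H2bc4).

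Among the other large falls, the tight junction gene Cldn1 fell by 1.05 on the log2 scale (SE 0.0493), Fcrl6, of the Fc receptor-like family, by 0.92 (SE 0.0440), and Ptpn22, a phosphatase that dampens antigen receptor signalling, by 0.90 (SE 0.0410). Ifi208, of the interferon-inducible p200 family, fell by 1.12, and the immunoglobulin constant region Ighg3 by 0.90. The lysophospholipid receptor P2ry10 fell by 0.72, the recombinase subunit Rag2 by 0.71, the fatty acid transporter Cd36 by 0.70, and Cth, which makes cysteine from cystathionine, by 0.70. Adjusted p for these 9 genes, Rgs18, Rgs1 and Bcor lay between 1.97e-06 (Rgs18) and 0.00189 (Rag2). Ly6f, Ifi208, P2ry10, Ighg3 and H2bc4 belong to families of close sequence, and their probes may read more than 1 member.

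**Figure D1:**
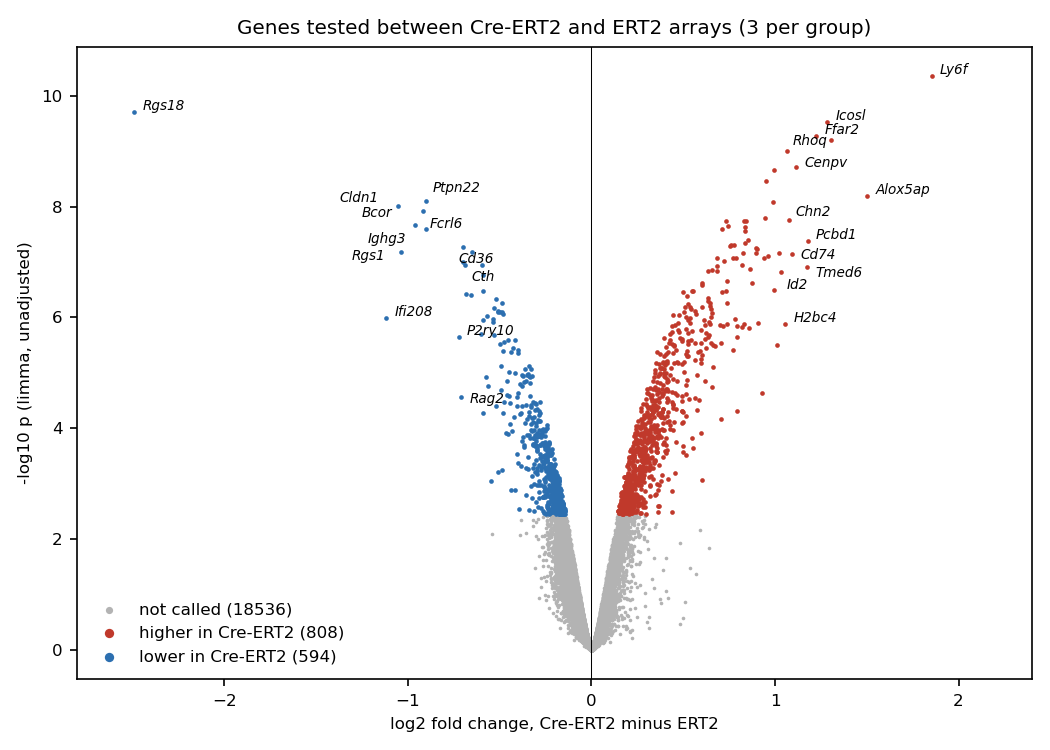
Log2 fold change of Cre-ERT2 minus ERT2 (x axis) against -log10 of limma's unadjusted p (y axis) for the 19938 genes tested. Red points are the 808 genes called higher, blue points the 594 called lower and grey points the genes not called. Rgs18 (-2.49) and Ly6f (1.85) lie farthest from 0 among labelled genes.

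**Figure D2:**
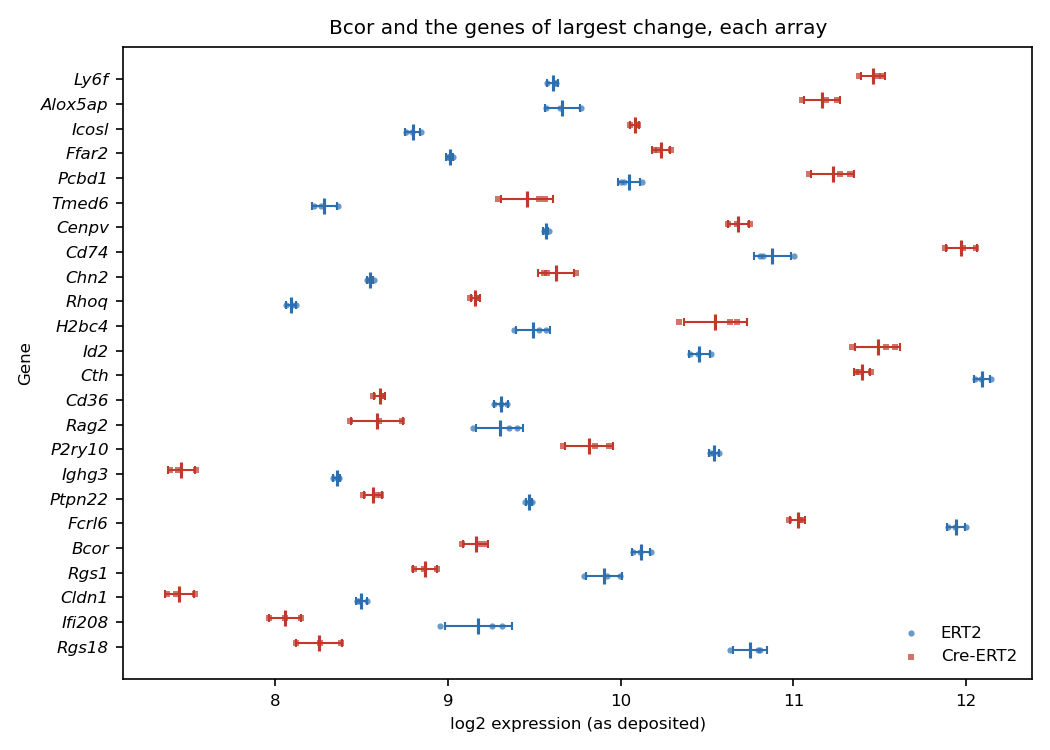
Log2 expression on each of the 6 arrays (x axis) for Bcor and the genes of largest change (y axis). Circles are ERT2 arrays, squares are Cre-ERT2 arrays, vertical ticks are group means and bars the SD over 3 arrays; Bcor lies at 10.12 in ERT2 and 9.16 in Cre-ERT2.

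Most called changes were small. The median absolute log2 fold change of called genes was 0.26, and the smallest was 0.14. Only 19 called genes changed by at least 1 on the log2 scale, 15 higher and 4 lower, and 179 changed by at least 0.5, 144 higher and 35 lower. Groups did not overlap for 5958 genes (29.9%), where chance gives 10% if the arrays are independent. The groups were also apart for all 1402 called genes, but a call largely requires this, so it adds no support. Of the called genes 57.6% were higher, and after cyclic loess between arrays 67.9% were. With array weights 39.4% were higher (1315 higher, 2024 lower), and at an adjusted p of 0.1 lower calls outnumbered higher calls (1190 to 1081). The count was 770 without ERT2 replicate 1, 934 without ERT2 replicate 2, 804 without Cre-ERT2 replicate 1 and 743 without Cre-ERT2 replicate 2.

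Of 29 measured genes induced by interferon, 13 rose, 3 fell and 13 did not pass (19 rose and 3 fell adjusted over the list alone), and the median log2 fold change was 0.19. Usp18, a protease that removes ISG15, rose by 0.65 (SE 0.0491, adjusted p = 0.000143), Oasl2, of the oligoadenylate synthetase family, by 0.60 (SE 0.0594), the RNA sensor regulator Dhx58 by 0.51 (SE 0.0881) and Parp14 by 0.50 (SE 0.0707). The members that fell, named after their values were seen, were Ifit2 (-0.37), Oas1a (-0.19) and Gbp3 (-0.17). Camera placed the list above other genes (adjusted p = 2.26e-12). Its adjusted p was 0.0901 with an estimated correlation.

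Of 30 measured genes of the amino acid response and unfolded protein response, 12 fell, 1 rose and 17 did not pass (16 and 1 adjusted over the list alone), with a median of -0.12. Trib3, a pseudokinase induced by ATF4, fell by 0.46 (SE 0.0523), Chac1, which degrades glutathione, by 0.44 (SE 0.0563), Sesn2 by 0.32 (SE 0.0645) and the mitochondrial folate enzyme Mthfd2 by 0.30 (SE 0.0487). Atf4 itself was at -0.28 (adjusted p = 0.00283, chosen after its values were seen), and the member that rose was the unfolded protein response factor Xbp1, at 0.23 (likewise chosen). The camera test gave adjusted p = 1.02e-05, downward, and adjusted p = 0.283 with an estimated correlation. The Sesn2 call ended without ERT2 replicate 2 or 3 or Cre-ERT2 replicate 1 or 2, at an adjusted p of up to 0.0779.

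Of 31 measured S-phase and E2F target genes 4 fell, 0 rose and 27 did not pass (18 and 0 adjusted over the list alone), with a median of -0.13. They were the cyclin Ccne1 (-0.24, SE 0.0415), the nucleotide enzymes Dut (-0.19, SE 0.0367) and Tk1 (-0.18, SE 0.0393), and the ribonucleotide reductase subunit Rrm2 (-0.18, SE 0.0355). By camera the list had adjusted p = 6.01e-07, downward, and adjusted p = 0.339 with an estimated correlation. Each of these 4 calls ended with at least 1 array left out: Ccne1 without ERT2 replicate 1 or Cre-ERT2 replicate 2 (adjusted p up to 0.0541), Dut without ERT2 replicate 1 or 3 or Cre-ERT2 replicate 1 or 2 (up to 0.0948), Tk1 with any array but Cre-ERT2 replicate 3 left out (up to 0.121), and Rrm2 without replicate 1 or 2 of either group (up to 0.0948). Of 29 measured mitosis genes 0 were called (camera adjusted p = 0.841, median -0.03). The spindle checkpoint kinase gene Bub1 was at -0.12 (adjusted p = 0.0851) and Birc5 at -0.13 (adjusted p = 0.162). Of 10 CDK inhibitor and ARF-p53 genes 0 were called (camera adjusted p = 0.223), with Mdm4 at -0.17 and Cdkn2b at -0.13. Of 28 MYC target and ribosome biogenesis genes 0 were called (camera adjusted p = 0.0593), with Polr1b at -0.15 (adjusted p = 0.0777) and Odc1 at 0.22 (adjusted p = 0.0805). The median of that list was -0.074, below -0.021 in random lists of genes matched on level.

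Of 27 p53 target genes 3 rose and 4 fell (camera adjusted p = 0.722). The antiproliferative gene Btg2 rose by 0.60, Trp53inp1 by 0.46 and Zmat3 by 0.33, and the kinase gene Plk3 fell by 0.57. The other members that fell were Sesn2 (-0.32) and, named after their values were seen, Rrm2b (-0.22) and Fas (-0.19). Of 23 regulators of apoptosis in the BCL2 family and caspases 4 rose and 0 fell: Casp6 (0.55), the BH3-only genes Bmf (0.37) and Bcl2l11 (0.33), and Bcl2 (0.25), which blocks apoptosis (camera adjusted p = 0.0960).

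Of 19 measured genes for homing and adhesion 5 rose, 0 fell and 14 did not pass (6 and 1 adjusted over the list alone). The chemokine receptor Ccr7 rose by 0.69 (SE 0.0415), the integrin Itgal by 0.64 (SE 0.0495), and the sphingosine phosphate receptor S1pr1 and the adhesion molecule Icam1 each by 0.37. Itga6, chosen after its values were seen, rose by 0.19. Camera gave adjusted p = 1.61e-05, upward, and adjusted p = 0.294 with an estimated correlation. Of 19 NF-kB target genes 3 rose and 0 fell (4 and 0 adjusted over the list alone): Ccl3 (0.53, SE 0.0526), Icam1 (0.37, SE 0.0547) and Tnf (0.32, SE 0.0499). The camera test gave adjusted p = 0.000146, upward, and adjusted p = 0.375 with an estimated correlation.

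Of 25 measured genes reported as BCL6 targets 5 rose, 2 fell and 18 did not pass (8 and 4 adjusted over the list alone), with a median of 0.04. Id2 (1.03), Ccl3 (0.53) and S1pr1 (0.37) rose and Tlr4, the receptor for lipopolysaccharide, fell by 0.53 (SE 0.0414). The other called members were Bcl2 (0.25) and, chosen after their values were seen, Ccnd2 (0.18) and Cd69 (-0.33). By camera the list had adjusted p = 0.0101, upward, and adjusted p = 0.283 with an estimated correlation. Among 12 PRC1.1 subunits and BCOR partners, Bcor fell and its relative Bcorl1 rose by 0.32 (SE 0.0433, adjusted p = 0.00308), and no other member was called over all genes (3 rose and 2 fell adjusted over the list alone). The list's median was 0.07 and its mean, which includes Bcor at -0.96, was -0.03. Camera (adjusted p = 0.136) and fry gave opposite directions, and neither was called. Of 22 other polycomb genes 2 rose and 1 fell: Pcgf2 (0.31), Jarid2 (0.21) and Phf19 (-0.19), with camera adjusted p = 0.544. The Pcgf2 call ended without ERT2 replicate 1 or 2 or Cre-ERT2 replicate 1 (adjusted p up to 0.0622), and that of Phf19 with any array but ERT2 replicate 2 left out (up to 0.131). Of 13 BCL6 corepressors and related repressors Mta3 rose by 0.23, a call lost with the mean of a gene's probe sets (adjusted p = 0.161), and camera gave adjusted p = 0.841. Of 22 HOX genes and cofactors Meis2 rose by 0.31 (camera adjusted p = 0.660).

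Of 25 B-lineage transcription factors 4 rose and 2 fell (7 and 4 adjusted over the list alone): Id2 (1.03), Spib, an ETS factor of B cells (0.79, SE 0.0478) and Erg (0.40) rose, and Id3 fell by 0.36. Sox4 (0.25) and Foxo1 (-0.26) were also called and were chosen after their values were seen. The list's median log2 fold change was 0.007, against -0.037 over all genes. Camera gave adjusted p = 0.0396, upward, and adjusted p = 0.490 with an estimated correlation. That call ended without ERT2 replicate 2 (adjusted p = 0.0667) or Cre-ERT2 replicate 3 (0.0812), after cyclic loess (0.0923), with the dimmest 30% of genes left out (0.112) and by fry (0.0544). For V(D)J recombination, 1 of 11 genes rose and 2 fell: terminal transferase Dntt rose by 0.86 (SE 0.0741) while Rag2 fell by 0.71 (SE 0.0876) and Rag1 by 0.38 (SE 0.0415), with camera adjusted p = 0.312. Of 14 pro-B and stem-cell-like surface genes 3 rose and 1 fell (camera adjusted p = 0.123). Il2ra rose by 0.94 (SE 0.0567), Flt3 by 0.56 and Cd24a by 0.19, while the interleukin 7 receptor chain Il7r fell by 0.60 (SE 0.0372). The Cd24a call ended with any array but Cre-ERT2 replicate 3 left out (adjusted p up to 0.171).

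Of 21 mature B cell and germinal centre genes, 6 rose and 5 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0593). Cd74 rose by 1.09, the follicle homing receptor Cxcr5 by 1.02 (SE 0.0604), lymphotoxin beta Ltb by 0.86 (SE 0.0551) and Ccr7 by 0.69, while Ms4a1, which encodes the B cell surface protein CD20, fell by 0.59 (adjusted p = 9.89e-05). The other members that rose were H2-DMa (0.55) and Cd40 (0.19). The other members that fell were H2-Ob (-0.20), Cr2 (-0.19), Fas (-0.19) and the class II MHC activator Ciita (-0.16). Ms4a1 and all of these other members were chosen after their values were seen. Of 22 genes of the pre-B cell receptor and its signalling 3 rose and 2 fell (4 and 3 adjusted over the list alone). The inhibitory receptor Cd22 rose by 0.27, the adaptor Pik3ap1 by 0.23 and the exchange factor Vav2 by 0.21, and the kinase Blk fell by 0.31, as did Fyn by 0.15 (chosen after its values were seen). The median of this list was 0.02. The camera test gave adjusted p = 0.0422, upward, and adjusted p = 0.533 with an estimated correlation. That call ended without ERT2 replicate 1 or 2 or Cre-ERT2 replicate 2 or 3 (adjusted p from 0.0516 to 0.106), after cyclic loess (0.0954), with the dimmest 30% of genes left out (0.118), with the mean of probe sets (0.0536) and by fry (0.310). The Vav2 call ended without ERT2 replicate 1 (adjusted p = 0.0578).

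Of 20 BCR-ABL1 and STAT5 target genes 6 rose and 2 fell (8 and 3 adjusted over the list alone). Cish, an inhibitor of cytokine signalling induced by STAT5, rose by 0.52 (SE 0.0447), Socs3 and the phosphatase Dusp4 each by 0.33, and Spred1, an inhibitor of RAS signalling, fell by 0.31, as did Egr1 by 0.25. By camera the list had adjusted p = 0.00598, upward, and adjusted p = 0.471 with an estimated correlation, and fry gave adjusted p = 0.0937. The Socs3 call was lost with the mean of its probe sets (adjusted p = 0.0814). Of 21 immediate early genes 3 rose and 2 fell (6 and 2 adjusted over the list alone): Btg2 (0.60), Jun (0.31) and Fosb (0.19, chosen after its values were seen) rose, and Atf3 (-0.27) and Egr1 (-0.25) fell. The median of the immediate early list was 0.03. Camera gave adjusted p = 0.0133, upward, and adjusted p = 0.533 with an estimated correlation. The list's call ended without ERT2 replicate 2 (adjusted p = 0.0867) or Cre-ERT2 replicate 1 (0.0818), with the dimmest 30% of genes left out (0.1003) and by fry (0.196). The Atf3 call ended with any array but ERT2 replicate 2 left out (up to 0.127), and that of Egr1 without ERT2 replicate 1 or 3 or Cre-ERT2 replicate 1 or 2 (up to 0.0892).

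Of 26 glycolysis and hypoxia genes 4 rose and 1 fell (camera adjusted p = 0.0952): the prolyl hydroxylase Egln3 rose by 0.65 (SE 0.0603), Aldoc by 0.39 and Pfkfb4 by 0.27, and Pfkp fell by 0.23. Slc2a3 rose by 0.16 and was chosen after its values were seen. Of 20 cholesterol synthesis genes 2 rose, Hmgcs1 by 0.18 and Insig1 by 0.16 (camera adjusted p = 0.123). Of 13 heat shock genes 1 rose, Hspa1a by 0.28 (camera adjusted p = 0.841). Of 12 histone genes 1 rose, H2bc4 (camera adjusted p = 0.544). The calls of Hmgcs1 and Insig1 each ended with any array left out (adjusted p up to 0.108 and 0.155), that of Pfkp without replicate 1 or 2 of either group (up to 0.0828), that of Pfkfb4 without ERT2 replicate 2 or 3 or Cre-ERT2 replicate 1 or 2 (up to 0.0694), and that of Hspa1a without ERT2 replicate 1 or 3 or Cre-ERT2 replicate 1 or 2 (up to 0.0747). Of 19 genes near Bcor on the X chromosome, Bcor and the NADPH oxidase subunit Cybb (-0.28) fell and Cask rose by 0.19 (camera adjusted p = 0.0952), and the Cask call ended with any array but ERT2 replicate 3 left out (up to 0.0822).

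**Figure D3:**
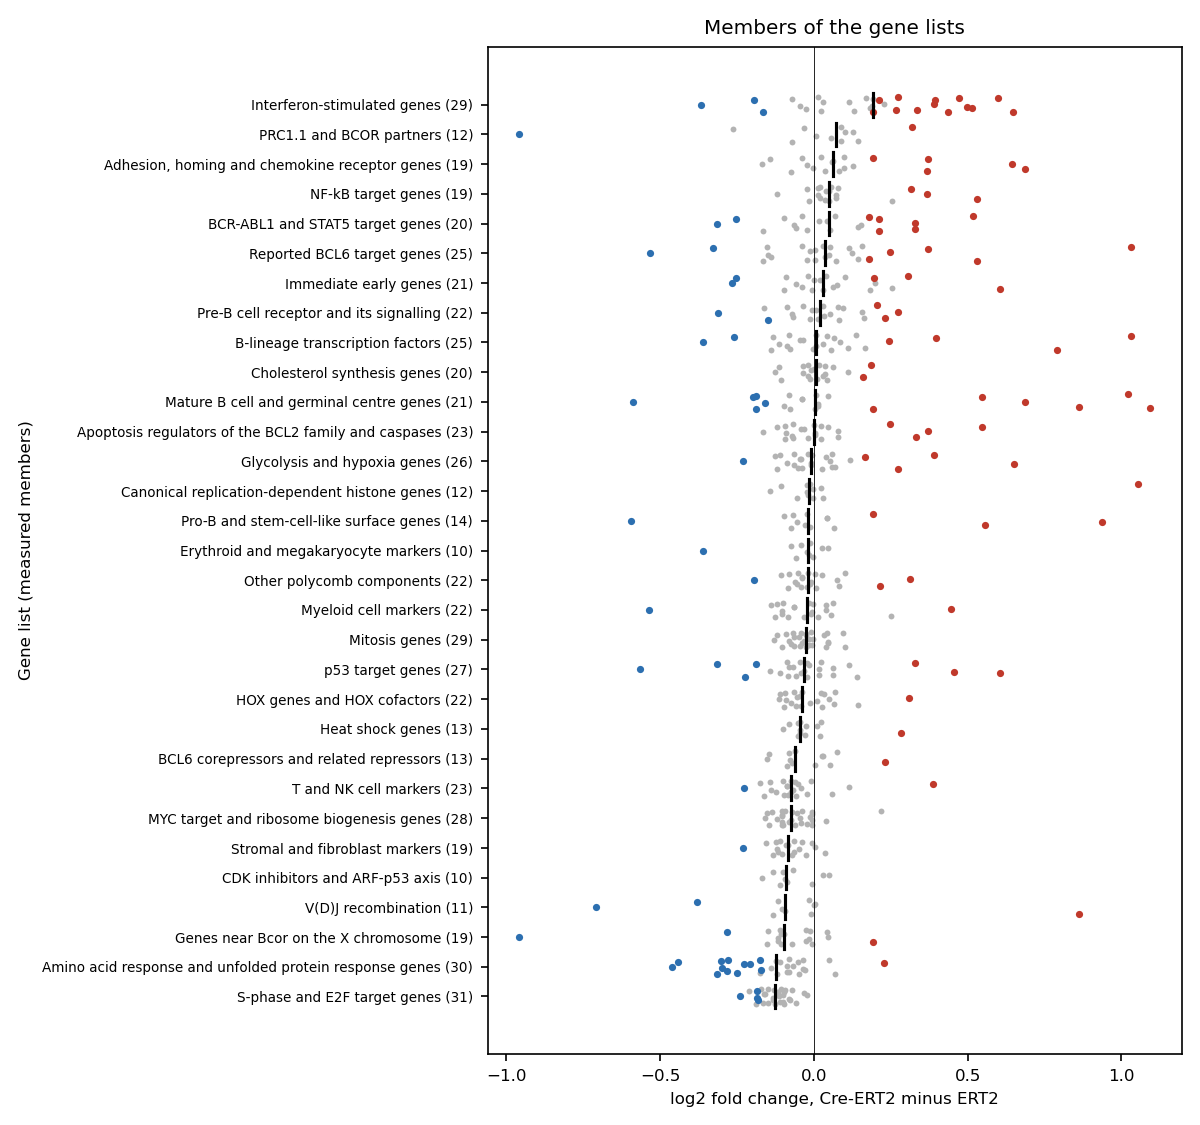
Log2 fold change (x axis) of each measured member of the 31 gene lists (y axis, number measured in brackets). Red and blue points are members called higher and lower, grey points were not called, and black ticks mark list medians, which run from 0.19 (interferon-stimulated genes) to -0.13 (S-phase and E2F target genes).

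Of 22 myeloid markers Lyz2 rose by 0.45 and Mrc1 fell by 0.54 (camera adjusted p = 0.841), and Cd68 was at 0.05 (adjusted p = 0.409). Of 23 T and NK cell markers Cd28 rose by 0.39 and Ncr1 fell by 0.23 (camera adjusted p = 0.123), and the marker levels of Cd5 (0.06) and Bcl11b (-0.10) did not pass. The Ncr1 call ended without Cre-ERT2 replicate 1 (adjusted p = 0.0529). Of 10 erythroid and megakaryocyte markers Car2 fell by 0.36 (camera adjusted p = 0.790), and Tfrc was at -0.02. Of 19 stromal and fibroblast markers Tagln fell by 0.23, and Vim and Col1a1 did not pass (adjusted p = 0.946 and 0.308). Camera placed that list below other genes (adjusted p = 0.0422, and adjusted p = 0.375 with an estimated correlation). The stromal call ended without ERT2 replicate 1 or 3 or Cre-ERT2 replicate 1 or 3 (adjusted p from 0.0695 to 0.0760), after cyclic loess (0.0689) and with the dimmest 30% of genes left out (0.0952). The Tagln call ended without ERT2 replicate 2 or 3 or Cre-ERT2 replicate 1 or 2 (up to 0.0762).

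In all, camera called 11 of the 31 lists, 8 upward and 3 downward. With the correlation estimated per list it called 0, with 4 lists at an unadjusted p under 0.05, and fry's directional test called 15. Fry, which does not compare a list with other genes, called 8 lists that camera did not. Upward these were apoptosis regulators (adjusted p = 0.0150), mature B cell genes (0.0246) and pro-B surface genes (0.0257). Downward they were genes near Bcor (0.00913), CDK inhibitors, MYC targets and V(D)J recombination (0.0150 each) and myeloid markers (0.0465). Median log2 fold changes of the upward lists were 0.0008 (apoptosis), 0.0035 (mature B cell) and -0.018 (pro-B). Their upward calls therefore do not show a rise of the typical member. The list of genes near Bcor includes Bcor itself, at -0.96, so part of its fall was set by the design. Fry tests against no change, and the median log2 fold change over all genes was -0.037. The myeloid median of -0.024 lay above that of random lists matched on level (-0.044), so its fall did not exceed theirs.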

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

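Probe sets that the gene tests left out also differed between the groups. They were tested with limma in a fit over all probe sets other than the control-like block. Of 1621 probe sets that name several genes, 79 were called higher and 28 lower in Cre-ERT2. Of 5529 probe sets with no listed gene outside that block, 59 were called higher and 39 lower. By comparison, 699 of 21789 probe sets with 1 gene were called higher and 410 lower in the same fit. In the control-like block of 6617 probe sets limma called 0, while 378 had an unadjusted p under 0.05 and the median log2 fold change was 0.07.

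Of the called probe sets with no listed gene, 8 were lower and 3 higher by at least 1 on the log2 scale. The 2 of largest change in each direction are given by number and were chosen after their values were seen. Probe set 10403079 was at -1.32 (SE 0.0465, limma adjusted p = 2.20e-05), with a mean log2 level of 11.30 ± 0.0640 in ERT2 and 9.97 ± 0.0417 in Cre-ERT2 (SD). Probe set 10403031 was at -1.24 (SE 0.0809, adjusted p = 0.000265). In the other direction, probe set 10429564 was at 1.25 (SE 0.191, adjusted p = 0.0115) and probe set 10397553 at 1.11 (SE 0.0855, adjusted p = 0.000608). These genes were not identified here.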

How the results depend on the processing

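Cyclic loess was chosen after the data were seen, and the other alternatives before the data were examined. Bcor was lower and called with the replicate block, trend, array weights and each normalization, and with each array left out, while its change of -0.96 lies short of a threshold of 1. Of the 1402 called genes, 0 changed sign after quantile normalization or cyclic loess. The replicate numbers did not pair the samples: deviations from group means correlated at 0.0506, -0.0946 and -0.26 for numbers 1 to 3. Across groups, ERT2 replicate 1 correlated best with its own number. ERT2 replicate 2 correlated best with Cre-ERT2 replicate 3 (0.311), and ERT2 replicate 3 with Cre-ERT2 replicate 1 (0.24). The replicate block does not model these last pairs. With the replicate block, limma called 805 genes (546 higher, 259 lower) and camera 11 lists, and 789 of the 1402 original calls were kept. Array weights gave 3339 genes (1315 higher, 2024 lower), and an adjusted p of 0.1 gave 2271 (1190 lower). Requiring a log2 fold change of at least 1 left 19 (15 higher, 4 lower), and treat against 0.2 left 222 (173 higher, 49 lower), by construction stricter tests. The count was 1823 with an intensity trend, 1156 after quantile normalization (1104 of the original calls kept), 1472 after median centring (1355 kept) and 1417 after cyclic loess (962 higher, 455 lower; 1259 kept). Leaving out each array gave 743 to 1341 genes (513 to 713 higher, 214 to 628 lower) and kept 734 to 1067 of the original calls. Fewer arrays were then fitted. Camera called 0 lists with an estimated correlation. The causes of the other changes were not tested. Of 94 called named genes, 73 were called in all settings run for them, and 19 lost the call with at least 1 array left out. Over the alternatives, 713 of 735 values of named genes kept their side of the threshold, 14 lost a call and 8 gained it. For lists, 212 of 248 did, 23 lost a call and 13 gained it. With arrays left out, 553 of 630 values of named genes and 171 of 186 of lists did. The probe signal over background was not used here, so its limit on dim genes is not known.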

Other observations

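The gene families described here, cyclic loess, and the tests on genes that do not overlap and genes at a distance of 10 were chosen after results were seen. The p53 target and mitosis lists were set before the data were examined, but their use to weigh explanations was chosen after. No enrichment of these families was tested. Of 36 interleukin receptor genes measured, 7 rose, 2 fell and most were not called by limma's test. Besides Il2ra, the decoy receptor Il1r2 rose by 0.82 on the log2 scale (SE 0.0512), Il4ra by 0.74 (SE 0.0383) and Il10ra by 0.65 (SE 0.0546), while Il7r and Il13ra1 (-0.23) fell. Of 10 Toll-like receptors, Tlr1 rose by 0.74 (SE 0.0620), Tlr9 by 0.65 (SE 0.0510) and Tlr6 by 0.22 (SE 0.0499), and Tlr4 fell. Of 20 TNF receptor superfamily genes 3 rose, the BAFF receptor gene Tnfrsf13c by 0.54 (SE 0.0453), Tnfrsf9 by 0.45 and Tnfrsf19 by 0.44, and 3 fell, Tnfrsf1a (-0.22), Tnfrsf22 (-0.18) and Tnfrsf26 (-0.17).

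Of 20 Rgs genes 3 fell and 1 rose, with Rgs8 at -0.49 (SE 0.0512) beside Rgs18 and Rgs1, and Rgs20 at 0.23. Of 9 P2Y receptor genes 3 fell and 0 rose: P2ry10, its neighbour in sequence P2ry10b (-0.66, SE 0.0478) and P2ry13 (-0.32, SE 0.0722). Of 8 genes of the interferon-inducible p200 family, Ifi208, Ifi206 (-0.46, SE 0.0698) and Ifi209 (-0.38, SE 0.0518) fell and 0 rose. In the list of interferon-stimulated genes 13 of 29 members rose and 3 fell. The difference between that list and the p200 family was not tested. Of 6 Fc receptor-like genes, Fcrl6 and Fcrls (-0.21) fell and Fcrla rose by 0.29. Of 5 Slamf genes, Slamf9 fell by 0.56 (SE 0.0655) and Slamf1 rose by 0.31 (SE 0.0463). Of 16 Ly6 genes, Ly6f was the called member.

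The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1402 genes and the highest other split 0, so that 1 of the 10 splits reached that count. Every other split mixes ERT2 and Cre-ERT2 arrays, so the group difference adds to the spread within its sides. The count of 0 therefore does not measure a chance level.

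Called genes that lie next to each other on a chromosome tended to change in the same direction. Among 141 pairs of neighbouring called genes whose symbols start differently, 108 (76.6%) shared a direction, against a mean of 51.1% and a highest value of 69.5% over 10000 shuffles of the directions (one-sided permutation p = 1e-04, the smallest these shuffles can give). Examples are Kdm7a (0.49) with Slc37a3 (0.53), Plxnc1 (0.90) with Cradd (0.51), and Capsl (-0.51) with Il7r (-0.60), chosen after their values were seen. Overlap of gene bodies is argued against as the whole source, since the share was 77.2% over 127 pairs without it. Relatedness was judged only by how the symbols start. Related genes with unlike symbols may remain among the pairs, so the share does not exclude shared sequence. Copy number segments of more than 10 genes are argued against as the main source. The share fell to 71.9% at a distance of 2 genes, 64.3% at 3, 58.6% at 5 and 41.4% at 10. Pairs were pooled over all chromosomes, so a few such segments, or shorter ones, are not excluded. A shared local response to lower Bcor, to Cre activity or to culture conditions may be a source. These cannot be told apart here. Transcription that runs on from a gene into its neighbour may be a source too, which was not tested.

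Camera placed interferon-stimulated genes above other genes in Cre-ERT2, a call lost with an estimated correlation (adjusted p = 0.0901). A level-dependent shift between arrays is argued against, because the list's median was 0.216 after cyclic loess. Cre activity itself, with DNA damage, stays open: the p53 target list had a median of -0.0337 with members that went both ways, and Cre-ERT2 was carried in every array with lower Bcor. The labels do not say that the arrays came from separate cultures, so a difference in culture conditions may go with Cre-ERT2 too. The effects of lower Bcor, Cre activity and culture conditions cannot be told apart here, and each may contribute.

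Camera placed amino acid response genes below other genes in Cre-ERT2, a call lost with an estimated correlation (adjusted p = 0.283). A level-dependent shift between arrays is again argued against, since the list's median was -0.111 after cyclic loess. Slower growth of the Cre-ERT2 cultures would lower S-phase and mitosis genes together. Camera called the S-phase list downward (adjusted p = 0.339 with an estimated correlation), with 4 of 31 members past the threshold, each lost with at least 1 array left out. Adjusted over the list alone, 18 members fell. The call of the S-phase list itself held with each array left out and by fry (adjusted p = 0.00913). The mitosis list had a median of -0.0253, close to -0.0210 in random lists matched on level, and how far slower growth would lower it is not known. Slower growth, culture conditions, Cre activity and lower Bcor may each contribute, and the data do not separate them.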
